A study of Mus musculus with 12 samples.

How the data were processed

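Total RNA was taken from the fallopian tubes of 6 female mice and measured on 12 arrays, 2 for each mouse. The arrays were 1-colour Illumina mouse BeadChips hybridised with biotin-labelled cRNA that was primed from poly(A) tails, per the labels' protocols. The labels call the 2 arrays of a mouse experimental repeats and do not say whether they share an RNA extract. The mouse was therefore the replicate, with 3 wildtype and 3 transgenic mice, and the log2 values of its 2 arrays were averaged before any test.

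The deposited values are a score: the authors standardized each array on its own, and per the submitters' processing notes GenomeStudio 1.6.0 was used. The notes used here give neither scale nor centring, so both were solved from the values. The low values of each column lie on a regular grid. Solving for 1 scale and 1 centre per array turned 100% of the values of every array into signals with 1 decimal, within a tolerance of 0.01 of the last digit. On simulated arrays the same solver returned 100% of the signals in each of 6 runs. That the standardization used log10 and each array's own mean and SD was learnt from 1 comparison by hand with an unnormalized scanner table of the series. The 12 signal columns and 12 detection columns of that table have names that match no single sample, and none of them entered a result. The medians of the deposited columns, repeat 1 and then repeat 2, were 0.106 and 0.0670 in the wildtype mouse of 7 weeks, 0.143 and 0.0788 at 8 weeks, and 0.153 and 0.0110 at 9 weeks. In the transgenic mice they were 0.190 and 0.0159 at 7 weeks, 0.222 and 0.0205 at 8 weeks, and 0.202 and 0.0559 at 9 weeks. Whether the scanner software subtracted a background is not given in the sources used here; the lowest recovered signal of an array lay between 59.1 and 87.8.

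The value table lists 25697 probes. Of these, 9033 were blank on all arrays, 0 were blank on some arrays, and 16664 had a value on every array and were tested without a further filter. The reason for the blanks is not given in the sources used here. In the platform annotation 15687 of the 16664 probes had 1 gene symbol, 0 had several and 977 had none. An Entrez identifier was matched to the current gene table for 15679 probes, and 0 symbols needed an update. The named probes stood for 11229 genes. A gene with several probes was represented by the probe with the highest mean over all arrays. Of 3115 genes with more than 1 probe, 4 had probes called in opposite directions.

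The recovered signals were quantile-normalized between arrays and put on the log2 scale with no background subtraction and no offset, in R 4.3.3 with limma 3.58.1. Signals near the array floor hold mostly background, so the fold of a dim gene is understated. The plan of neqc and a filter on detection p needed detection values matched to samples, and was replaced by this setting. Differences were tested with lmFit and eBayes, two-sided, at a Benjamini-Hochberg adjusted p below 0.05 over all tested probes. The genotype fit had 4 residual degrees of freedom over the 6 mouse means. The genotype by age fit took age in weeks as a number and had 2, and the fit of a shared age trend had 3. Differences at a single age rest on 1 mouse of each genotype and carry no test. Signals were recovered with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

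A total of 27 gene lists was fixed: mitosis, S phase and E2F targets, p53 targets, DNA repair, histones, interferon response, antigen presentation, estrogen-responsive genes, immediate early and stress genes, ribosomal proteins, oxidative phosphorylation, glycolysis, Müllerian development, epithelial-mesenchymal transition, Wnt, Notch and Hedgehog signalling, and markers of ciliated cells, oviduct secretory cells, epithelium, smooth muscle, fibroblast matrix, endothelium, macrophages and myeloid cells, lymphocytes, adipocytes, mesothelium, ovary and erythroid cells. Each was tested with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives, adjusted over the 27 lists. Members were also counted with p adjusted over the list alone. The genes named in the text were taken by rule. The rule took the 12 largest differences each way among genes past the threshold with 1 sign at all 3 ages, leaving out clone and model names. It also took 25 fixed genes, and in each list up to 4 members, the 2 highest and 2 lowest past the threshold or the 2 lowest p where none passed. For the interaction and the age trend it took the 3 lowest p where none passed. The groups, tests, lists, naming rule and most alternatives were chosen before the data were examined. Genes named outside the rule are said to be so, apart from Psmb8 and Psmb9, named for their place in more than 1 list.

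On simulated values for 16664 probes with 200 changed, the genotype test recovered 99% of the changes of log2 1 and 100% of those of log2 2, with 10 false among 209 calls. The interaction test recovered 91% and 100% of changes of these sizes per week, with 17 false among 208 calls, and the age test 100% and 100%, with 15 false among 215. Camera called a simulated list of 30 probes shifted by 0.5 and 0 of 20 unshifted lists. Those simulated genes vary independently, which the measured genes do not. Their noise took the spread of the genotype fit, and the 200 planted changes eased the adjusted threshold. These shares are therefore not the power of the tests on the measured values. There Hsd11b1 changed by -1.07 per week and did not pass the limma interaction test (adjusted p = 0.687).

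The labels number the repeats 1 and 2 in every mouse. The difference between a mouse's repeats correlated across probes in all 15 pairs of mice, with r from 0.109 to 0.638, and the second principal component separated the numbers. The repeat number therefore marks a difference that the mice share. Each mouse has both repeats, so the part of this difference that both genotypes share cancels in the genotype comparison. A part that differs by genotype does not cancel, as for the fat gene Adipoq, chosen after its values were seen. A fit to all 12 arrays with the replicate block and the mouse as a random block is given where it changes a call. Deviations of the transgenic and wildtype mouse of 1 age correlated with r of 0.324 at 7 weeks, 0.0964 at 8 weeks and -0.0707 at 9 weeks, so age does not pair all the mice. No slide or scan date was matched to a sample here, and no such batch was tested. The alternatives covered other scalings, removal of dim probes, the handling of repeats, age as a block, other variance models, each mouse or age left out, stricter thresholds and other list tests.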

Results

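The fallopian tubes of 3 wildtype C57BL6 and 3 mogp-TAg female mice were profiled, with 1 mouse of each genotype at the ages of 7, 8 and 9 weeks. The mogp-TAg mouse carries the large T antigen of the SV40 virus under the promoter of the mouse oviductal glycoprotein gene, which is active in the secretory epithelium of the tube. Large T antigen binds and inactivates the RB family and p53. The series title presents the strain as a model of ovarian cancer arising from the tube, and the comparison asks which genes differ between transgenic and wildtype tubes at these ages. The viral transgene was not analysed here. Each mouse was measured on 2 arrays, and the median signal of an array ran from 136.9 to 332, higher in repeat 1 than in repeat 2 in every mouse. The number of mice, 3 per genotype, limits the precision.

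Genes of cell division were among the largest increases in the transgenic tubes. Top2a, the topoisomerase that untangles chromosomes before mitosis, rose 11.3-fold (log2 3.50, SE 0.30, limma adjusted p = 5.04e-04, n = 3 mice per genotype), and Mcm5, a subunit of the replicative helicase, rose 10.4-fold. The spindle midzone protein Prc1 rose 16.7-fold and the centromeric histone Cenpa 9.49-fold. The largest rise was that of Prap1, a secreted proline-rich acidic protein, at log2 5.18 (SE 0.50, adjusted p = 6.90e-04). Of the measured markers, 38 of 47 for ciliated cells, 9 of 12 for mesothelium and 13 of 26 for smooth muscle fell, and 29 of 37 interferon response genes rose. These 4 lists passed camera at its preset correlation and not with an estimated one (adjusted p = 0.335 for each). In all, 1748 probes of 1292 genes were higher and 1822 probes of 1488 genes were lower in the transgenic tubes by limma, at an adjusted p below 0.05, with 5921 probes at an unadjusted p below 0.05. All 2573 genes called by their chosen probe differed in 1 direction at all 3 ages. A call on these same 6 mouse means nearly requires that, so it adds no support.

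Among mitotic genes, 42 of 43 measured members were higher and 0 lower over all probes, and 43 were higher adjusted over the list alone. The median log2 difference was 2.30, and the list mean was 2.22 ± 0.30 in the transgenic mice against 0 ± 0.19 in the wildtype mice (SD, n = 3). Prc1 (4.06) and Pbk (3.63), a mitotic kinase, led the list, while Ube2c (0.39) and Smc2 (0.38) rose least and lay near the array floor. Camera placed the list above other genes (adjusted p = 1.73e-34, and adjusted p = 0.335 with an estimated correlation). Of 49 S phase and E2F target genes, 47 were higher and 0 lower (48 adjusted over the list alone), with a median of 1.86 and camera adjusted p = 6.76e-36 (adjusted p = 0.335 with an estimated correlation). Mcm5 (3.38) and Mcm10 (3.07), a replication initiation factor, led, and Prim1 (0.54) and Dscc1 (0.49) rose least and lay near the array floor. DNA repair genes followed, with 21 of 33 higher and 1 lower (23 and 2 adjusted over the list alone), a median of 0.63 and camera adjusted p = 1.80e-10 (adjusted p = 0.384 with an estimated correlation). The recombination genes Rad54b (3.06) and Rad54l (2.30) rose most and Parp1 (0.42) least. The lower member, the checkpoint kinase Chek2 (-0.76), had 1 probe called higher and 1 called lower.

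**Figure D1:**
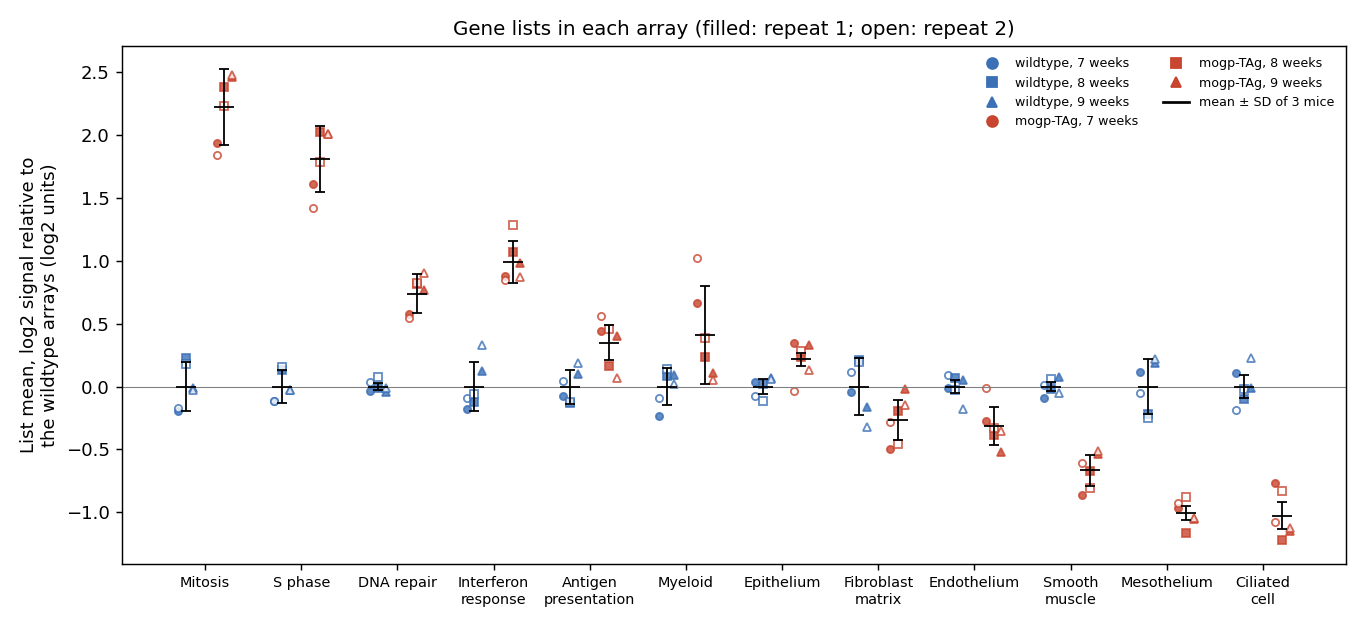
Mean log2 signal of 12 gene lists on each array, relative to the mean of the wildtype arrays, with filled symbols for repeat 1, open symbols for repeat 2, and black bars for the mean ± SD of 3 mice. The mitosis mean of every transgenic array lies between 1.84 and 2.48, and the ciliated cell mean between -1.22 and -0.76.

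Of 25 genes fixed beforehand for the RB and p53 pathways, proliferation and tubal cell types, 21 were measured, of which 9 were higher and 3 lower over all probes, and 10 higher and 4 lower adjusted over the list alone. Trp53, Mki67, Muc16 and Epcam were not analysed here. The transcription factor E2f1, released when RB is lost, rose by log2 2.69 (SE 0.19, adjusted p = 3.12e-04), and Foxm1 rose by 1.94. The Cdk inhibitor gene Cdkn2c rose by 2.36 (SE 0.10, adjusted p = 7.96e-05), and Cdkn2a, whose locus encodes p16 and ARF, by 0.88 from a signal near the floor. Rb1 rose by 0.56 and its relative Rbl1 by 1.28, and Rbl2 differed by 0.09 (adjusted p = 0.464). The Polycomb methyltransferase Ezh2 rose by 1.78 and the microtubule regulator Stmn1 by 2.49. The p53 targets Cdkn1a (0.30, adjusted p = 0.220; 0.47 and 0.0168 with array quality weights) and Mdm2 (-0.09, adjusted p = 0.648) did not pass, nor did Ccne1 (0.17, adjusted p = 0.163) or Myc (0.18, adjusted p = 0.152). Ovgp1, the gene whose promoter drives the transgene, was among the bright signals in both genotypes and differed by -0.24 (adjusted p = 0.0831); it passed under normexp with median scaling (-0.54, adjusted p = 0.00763) and on the deposited values (-0.43, adjusted p = 0.0427). Pax8, a secretory cell factor, differed by 0.36 (adjusted p = 0.0845), and the hormone receptors Esr1 and Pgr by -0.11 (adjusted p = 0.635) and 0.34 (adjusted p = 0.549). The lower genes were Wt1 (-2.26, SE 0.38, adjusted p = 0.00638), Msln (-0.87) and the ciliogenesis factor Foxj1 (-0.49, adjusted p = 0.0367).

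**Figure D2:**
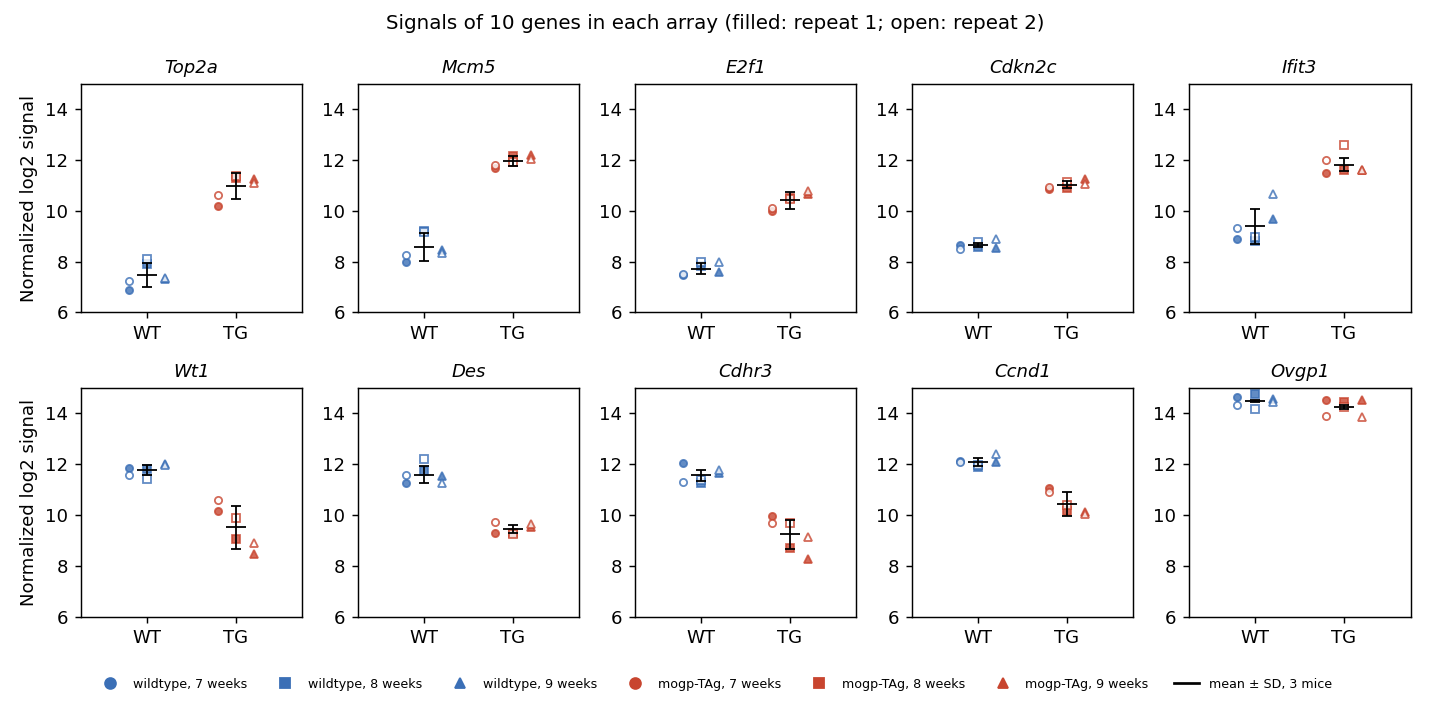
Normalized log2 signal of 10 genes on each array by genotype, WT for wildtype and TG for mogp-TAg, with filled symbols for repeat 1, open symbols for repeat 2, and black bars for the mean ± SD of 3 mice; the genes were chosen after their values were seen. Top2a lies between 6.89 and 8.09 on the wildtype arrays and between 10.20 and 11.37 on the transgenic arrays.

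Markers of ciliated cells were lower across most of the list: 38 of 47 fell and 0 rose (39 adjusted over the list alone), with a median of -1.02 and camera adjusted p = 1.06e-18 (adjusted p = 0.335 with an estimated correlation). The cadherin-related Cdhr3 (-2.33, SE 0.27) and the axonemal dynein chain Dnaic1 (-2.07, SE 0.13) fell most, and Bbs5 (-0.37) and Foxj1 (-0.49) least. Foxj1 lay near the array floor, with a signal of 142 in transgenic and 200 in wildtype tubes, so its fold is understated. Secretory cell markers moved both ways. Of 22 measured, 3 rose and 3 fell (the same numbers adjusted over the list alone), with a median of 0.06 and camera adjusted p = 0.456. Over all genes 2573 of 11229 were called by their chosen probe, and this list lay near that share. The p53, glycolysis, Müllerian, epithelial-mesenchymal transition and Wnt, Notch and Hedgehog lists, given below, lay near or under it too. So did the epithelial, fibroblast matrix, adipocyte, lymphocyte, ovary, erythroid, estrogen-responsive, immediate early and stress, ribosomal protein and oxidative phosphorylation lists. The anion exchanger Slc26a4 (2.07) and the secreted Wfdc2 (1.10) rose, while the chloride channel Cftr (-1.43) and the matrix protein Chad (-2.04) fell. Slc26a4 lay near the array floor in the wildtype tubes and Chad in the transgenic tubes. General epithelial genes had 5 of 29 higher and 1 lower (5 and 1 adjusted over the list alone; median 0.06, camera adjusted p = 0.137). These included Cdh16 (3.15), the protease St14 (0.84) and Tjp3 (0.44), with Myo5b (-0.63) lower.

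Smooth muscle markers fell in 13 of 26 cases and rose in 0 (15 and 0 adjusted over the list alone), with a median of -0.54 and camera adjusted p = 1.16e-05 (adjusted p = 0.335 with an estimated correlation). The amine oxidase Aoc3 (-2.22) and the intermediate filament gene Des (-2.14) fell most, and the contractile regulators Cald1 (-0.54) and Cnn1 (-0.38) least. Cnn1 lay near the array floor. Mesothelial markers fell in 9 of 12 cases and rose in 0 (10 and 0 adjusted over the list alone; median -0.84, camera adjusted p = 4.68e-06, adjusted p = 0.335 with an estimated correlation). Wt1 and Upk3b (-1.98) fell most, Lrrn4 (-0.80) and Rspo1 (-0.50), both near the array floor, least. Among endothelial markers 5 of 22 fell, with Esam (-0.92) and Flt1 (-0.73), and 2 rose, Sox7 (0.94) and Gpihbp1 (0.59); 10 fell and 2 rose adjusted over the list alone. Their median was -0.42 and camera adjusted p = 0.0132 (adjusted p = 0.673 with an estimated correlation and 0.0763 with the replicate block; 4.64e-04 to 0.187 over the other alternatives). Fibroblast matrix genes went both ways, with 2 of 33 higher and 5 lower (5 and 11 adjusted over the list alone; median -0.21, camera adjusted p = 0.307). Mfap5 (1.39) and the collagen cross-linker Lox (0.76) rose, and Loxl1 (-1.31) and Dpt (-1.91) fell. Adipocyte genes had 3 of 16 lower, Plin4 (-2.02), Cidea (-1.49) and Thrsp (-1.33), and 0 higher (3 and 0 adjusted over the list alone; median -0.16, camera adjusted p = 0.0825; median -0.29, adjusted p = 0.0476 under normexp with median scaling). The fat hormone Adipoq, chosen after its values were seen, differed between the repeats of each wildtype mouse, lower in repeat 2 by -3.11, -2.73 and -2.04 at 7, 8 and 9 weeks, and by -0.25, 0.21 and 0.13 in the transgenic mice. This repeat difference varies by genotype, so averaging the repeats leaves part of it in the adipocyte differences.

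Of 37 interferon response genes, 29 rose and 0 fell (31 adjusted over the list alone). Their median was 0.99, and camera adjusted p = 9.78e-17 (adjusted p = 0.335 with an estimated correlation). Ifit3 (2.42, SE 0.32) and Oas2 (2.39, SE 0.24), antiviral effectors induced by interferon, rose 5.34-fold and 5.23-fold, and Cxcl9 (0.33) and Oas1a (0.29) rose least. Oas1a lay near the array floor. Antigen presentation genes, which share Psmb8, Psmb9 and Tap1 with that list, had 12 of 23 higher and 2 lower (13 and 2 adjusted over the list alone; median 0.42, camera adjusted p = 0.0133, adjusted p = 0.673 with an estimated correlation). H2-Q7 and H2-D1 of class I rose, 3.04-fold and 2.67-fold, and the class II gene H2-Ob (-0.97) and the class II activator Ciita (-0.42) fell. H2-Ob and Ciita lay near the array floor in the transgenic tubes. The list had an adjusted p of 0.216 without the 7-week transgenic mouse (4.33e-04 to 0.243 over the other alternatives). Macrophage and myeloid markers had 7 of 26 higher and 2 lower (11 and 3 adjusted over the list alone; median 0.45, camera adjusted p = 0.00345, adjusted p = 0.673 with an estimated correlation). Ms4a7 (1.40) and Lyz2 (0.97) rose, and Mrc1 (-0.67) and Cd163 (-0.97), scavenger receptors of resident macrophages, fell. Cd163 lay near the array floor in the transgenic tubes. The median was 0.13 (adjusted p = 0.176) without both 7-week mice (adjusted p from 1.59e-05 to 0.256 over the other alternatives). The neutrophil gene S100a8, chosen after its values were seen, was higher in repeat 2 than in repeat 1 by 2.86 in the 7-week transgenic mouse and by 2.33 in the 8-week wildtype mouse. In lymphocyte genes 1 of 18 rose, the chemokine Ccl5 (1.02), and 0 fell (1 and 0 adjusted over the list alone; median 0.12, camera adjusted p = 0.202).

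**Figure D3:**
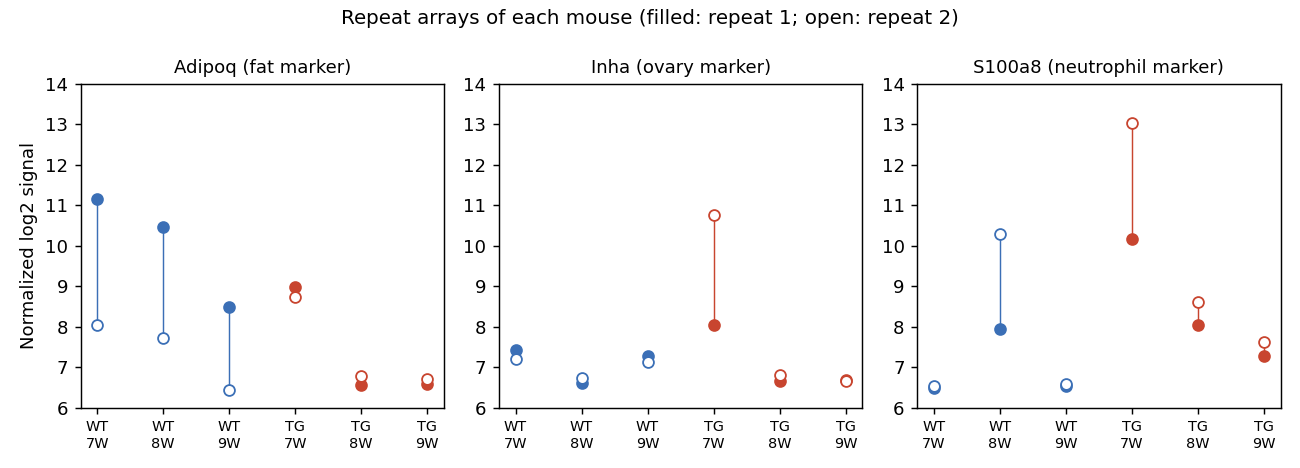
Normalized log2 signal of Adipoq, Inha and S100a8 in both repeat arrays of each mouse (WT for wildtype, TG for mogp-TAg; 7W, 8W and 9W for the age; filled for repeat 1, open for repeat 2), chosen after their values were seen. Adipoq was 8.48 or more in repeat 1 of the wildtype mice and 8.04 or less in their repeat 2, and Inha and S100a8 were highest in repeat 2 of the 7-week transgenic mouse, at 10.76 and 13.03.

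The p53 targets had 5 of 31 higher and 2 lower (5 and 2 adjusted over the list alone), with a median of -0.03, a mean of 0.00 and a camera direction of up (adjusted p = 0.748). Tap1 (1.02), also an interferon target, and Ddb2 (0.82) rose, and Zmat3 (-0.68) and Ptprv (-0.83) fell. Ptprv lay near the array floor in the transgenic tubes. Of 29 histone genes 11 rose and 9 fell (15 and 9 adjusted over the list alone; median 0.24, camera adjusted p = 0.137), from H2ac7 (3.73) and H2ac15 (3.69) to H2bc4 (-1.32) and H2bc6 (-1.36). Estrogen-responsive genes had 3 of 21 higher and 1 lower (3 and 1 adjusted over the list alone), with a median of -0.08, a mean of 0.02 and a direction of up (adjusted p = 0.454). Sprr2f (1.05; adjusted p = 0.0610 with the replicate block), Muc1 (0.83) and Clca1 (0.60) rose, and the G1 cyclin Ccnd1 fell by 1.64 (SE 0.22, adjusted p = 0.00264). Oxidative phosphorylation genes had 6 of 42 lower and 0 higher (5 and 0 adjusted over the list alone), from Cox8a (-0.31) and Uqcrb (-0.45; adjusted p = 0.0644 with the replicate block) to Ndufb5 (-0.69) and Ndufa1 (-0.74). Their median was -0.21 and camera adjusted p = 0.0133 (adjusted p = 0.673 with an estimated correlation, 0.0763 with the replicate block; 3.98e-04 to 0.328 over the other alternatives). In glycolysis 1 of 17 rose, hexokinase Hk2 (2.83-fold), and 2 fell, Slc2a1 (-0.57) and Eno2 (-0.59), the same numbers adjusted over the list alone (median -0.10, camera adjusted p = 0.621). In Müllerian development 2 of 15 rose, Hoxa9 (0.63) and Meis1 (0.45), and 1 fell, Hoxa7 (-0.87), again the same numbers over the list alone (median 0.06, camera adjusted p = 0.327).

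Epithelial-mesenchymal transition genes had 2 of 15 higher, Itgav (1.10) and Mmp7 (0.63), and 2 lower, Zeb2 (-0.52; adjusted p = 0.0676 with the replicate block) and Vim (-0.67), the same numbers adjusted over the list alone, with a median of -0.05, a mean of 0.01 and a direction of down (adjusted p = 0.995). In Wnt, Notch and Hedgehog signalling 3 of 26 fell, Jag1 (-0.44), Sfrp1 (-0.73) and Hey1 (-0.75), and 0 rose (3 and 0 over the list alone; median -0.12, camera adjusted p = 0.307). Among immediate early and stress genes the chaperone partner Dnajb1 (0.52) rose and Hsph1 (-1.28) fell, 1 and 1 of 21 on either adjustment (median 0.13, camera adjusted p = 0.317). In the ovary list 1 of 23 rose, Ptgfr (0.45), and 0 fell, on either adjustment (median 0.11, camera adjusted p = 0.258), and the ovarian gene Inha, chosen after its values were seen, was higher by 2.70 in repeat 2 than in repeat 1 of the 7-week transgenic mouse. The erythroid list had 5 measured genes, of which carbonic anhydrase Car2 (1.22) rose and 0 fell, on either adjustment (median 0.01, camera adjusted p = 0.307). Of 33 ribosomal protein genes 0 rose and 0 fell on either adjustment by limma (median -0.06, camera adjusted p = 0.621); the lowest p belonged to Rpl24 (-0.25, adjusted p = 0.147) and Rplp0 (-0.32, adjusted p = 0.156). Under normexp with median scaling the list passed camera (median -0.18, adjusted p = 0.0121) and Rpl24 was lower (-0.43, adjusted p = 0.0260), as it was with array quality weights (-0.37, adjusted p = 0.0138).

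The spindle protein Nusap1, a further mitotic gene, rose by 3.20, and outside the lists the remaining large rises were those of H2ac12 (3.66), H2ac10 (3.29) and the PCNA-binding Pclaf (3.32). The largest falls were in Dcpp2 (-4.80, SE 0.32), Dcpp3 (-4.71), Ghrh (-3.13), the protease inhibitor Timp4 (-2.99) and Dcpp1 (-2.98). The secreted demilune cell proteins Dcpp2, Dcpp3 and Dcpp1 had transgenic signals of 104, 93.9 and 94.9, near the array floor, so these folds are understated. The Dcpp genes and the H2A genes are near-identical copies whose probes can share transcripts. Serpinb11 (-2.86), the small GTPase Diras2 (-2.84) and Mmd2 (-2.77) followed. Transgenic signals of Ghrh (120), Timp4 (143), Serpinb11 (108), Diras2 (146) and Mmd2 (120) also lay near the floor. Their folds are understated too, and the order of the largest falls depends in part on the floor. Aoc1 (-2.42), the matrix protein Spon2 (-2.33) and Vpreb3 (-2.31, SE 0.10) completed the lower end. The counts depended on which mice entered, with 873 higher and 858 lower probes without the 8-week transgenic mouse and 1092 and 1146 without the 9-week wildtype mouse. Of the 27 lists, 11 passed camera at its preset correlation, 0 with an estimated correlation and 8 with fry, which asks only whether the genes of a list move 1 way.

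Whether the genotype difference changed between 7 and 9 weeks was the question of the second comparison. The mitotic median difference was 2.07, 2.22 and 2.55 at 7, 8 and 9 weeks, and that of ciliated cell markers was -0.95, -1.02 and -1.29. Wt1 was lower by -1.32, -2.16 and -3.31 and Ccnd1 by -1.11, -1.66 and -2.14 at these ages, each from 1 mouse of each genotype. Other differences narrowed, with Prap1 at 5.79, 5.99 and 3.75 and Ms4a7 at 1.80, 1.76 and 0.62. These examples were picked outside the naming rule for this comparison, and no common direction follows from them. Across all 16664 probes the differences of 2 ages correlated with r = 0.790 (7 and 8 weeks), 0.751 (7 and 9) and 0.758 (8 and 9), where probes are not independent replicates. By limma, 0 probes passed for a change of the difference with age, with 1072 at an unadjusted p below 0.05 and a lowest adjusted p of 0.687. The lowest p belonged to Hsd11b1 (-1.07 per week), which makes active glucocorticoid, Wfdc17 (-0.94) and Ddah1 (-0.97). In 15 of 19 alternatives 0 probes passed. Without the 7-week wildtype mouse 254 passed, and without the 9-week wildtype mouse 12. Without 1 mouse the fit has 1 residual degree of freedom, and the line of that genotype runs exactly through its 2 mice. With the mouse as a random block 7 passed, and 4 with the replicate block besides. Those fits count repeat arrays partly as separate mice. Their consensus correlation within a mouse, in the genotype fit, was 0.088, and 0.311 with the replicate block.

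The third comparison asked whether genes shifted with age in both genotypes alike. The lowest p belonged to the mitochondrial carrier Slc25a33 (-0.77 per week), the glucocorticoid-induced Tsc22d3 (-0.59) and Csrnp1 (-0.38), and none passed (adjusted p = 0.453 for each). By limma 0 probes passed, with 1324 at an unadjusted p below 0.05. By camera at its preset correlation 13 of the 27 lists passed for a shared slope with age, and 0 with an estimated correlation. The fit gives both genotypes 1 slope, so a passing list need not move alike in both. In the wildtype mice the myeloid mean was -0.24 and -0.09 at 7 weeks (repeat 1 and 2) and 0.09 and 0.02 at 9 weeks. In the transgenic mice it was 0.66 and 1.02, then 0.11 and 0.05. Mitosis, S phase, DNA repair, interferon response, myeloid and ovary lists also passed camera for a change of the genotype difference with age. The mitosis list had a median of 0.19 per week (adjusted p = 5.29e-13, and 0.570 with an estimated correlation) and the S phase list 0.15 (adjusted p = 2.71e-12, and 0.586). Histone (0.13), interferon response (0.10), DNA repair (0.072), glycolysis (0.065), oxidative phosphorylation (0.055) and smooth muscle (0.044) lists had medians above 0. Ovary (-0.16), adipocyte (-0.15), endothelium (-0.11), immediate early and stress (-0.091) and myeloid (-0.062) lists had medians below 0; the adjusted p of these 11 lay between 4.04e-06 and 0.0426, and between 0.570 and 0.680 with an estimated correlation. In 17 of 19 alternatives 0 probes passed. In the fit to 12 arrays with the mouse as a random block 15 passed, and 20 with the replicate block besides. Those fits count repeat arrays partly as separate mice.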

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

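The tests of dilution, of immune cell number and of other groupings of the mice, and the neutrophil and ovarian genes weighed for the 7-week transgenic mouse, were chosen only after the results they bear on were seen. In 11 gene lists the genotype difference changed with age by camera at its preset correlation, and in none of them with an estimated correlation. The values are medians of the change in log2 difference per week. The mitosis list changed by 0.24 (adjusted p = 2.08e-07, and 0.612 with an estimated correlation) and the S phase list by 0.20 (adjusted p = 6.46e-09, and 0.612). DNA repair genes changed by 0.15 (adjusted p = 4.39e-05, and 0.612), fibroblast matrix genes by 0.25 (adjusted p = 4.13e-05, and 0.612) and ciliated cell markers by -0.18 (adjusted p = 6.89e-07, and 0.612). Interferon response genes changed by -0.13 (adjusted p = 0.00918, and 0.827), antigen presentation genes by -0.25 (adjusted p = 0.00115, and 0.612) and macrophage and myeloid markers by -0.40 (adjusted p = 1.92e-13, and 0.612). The median difference of the antigen presentation list itself was 0.48, 0.41 and 0.48 at 7, 8 and 9 weeks, with no steady decline, and that of the interferon list 0.89, 1.25 and 0.63. Ovary markers changed by -0.29 (adjusted p = 4.22e-05, and 0.612), and by -0.04 (adjusted p = 0.0334) without the repeat 2 array of the 7-week transgenic mouse. Lymphocyte genes changed by -0.071 (adjusted p = 0.0209, and 0.612; -0.044, adjusted p = 0.210 without that array) and ribosomal protein genes by -0.072 (adjusted p = 0.0209, and 0.612; -0.11, adjusted p = 0.00730 without that array). Without it smooth muscle markers passed as well, at 0.13 (adjusted p = 0.00486, and 0.563 with an estimated correlation; 0.0863 with all arrays). With an estimated correlation the adjusted p without that array was 0.737 for ovary markers and 0.630 for lymphocyte and for ribosomal protein genes. Each age has 1 mouse per genotype, so a change with age is also a difference between single mice.

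List calls at the preset correlation also arose in other groupings of the mice. Of the 10 splits of the 6 mice into 3 and 3, 5 put as many lists past camera's threshold as the genotypes did, with 11 lists for the genotypes and 14 as the highest of the others. For probes the genotype split called 3570 and every other split 0, so 1 of the 10 splits gave as many. With 10 splits neither share can go below 0.1. Every other split sets 2 mice of a genotype against 1, so it carries part of the genotype difference into its list calls, and the rest of that difference widens the spread within its groups and holds down its probe calls. Neither number is therefore a reference for what chance alone gives. Taken list by list, mitosis, S phase, DNA repair, ciliated cell, smooth muscle, mesothelium and interferon response had their lowest p in the genotype split. Every other split holds only part of the genotype difference, so a list with a steady difference nearly has to rank so. That ranking therefore adds no support. Endothelium, myeloid, antigen presentation and oxidative phosphorylation lists had lower p in at least 1 other split.

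Ciliated cell markers were lower in the transgenic tubes (median -1.02), and dilution by other cells would lower the markers of every cell type that did not expand by a like amount. Over members above the median signal, fibroblast matrix genes lay above ciliated cell markers by 0.96 (SE 0.27), which argues against an equal dilution of both. Whether fibroblasts expanded was not measured, so this gap cannot exclude dilution as the whole cause. The median difference of the fibroblast list was -0.33, -0.38 and 0.20 at 7, 8 and 9 weeks. Markers of other cell types were lower too. The 7 bright mesothelial markers fell by as much (-1.32, SE 0.19, against -1.27, SE 0.10 for ciliated cell markers). Smooth muscle markers were lower by less (-0.92, SE 0.10) and endothelial markers least of these (-0.43, SE 0.11). Dilution may therefore account for at least part of the fall. Bright adipocyte genes averaged -0.83 (SE 0.31), but that list did not pass and its gene Adipoq differs between repeats. The choice among the scalings used does not account for the lower ciliated cell markers, since their highest median under the other scalings was -0.99. All of these bring the arrays to a common centre or distribution, so a fault of that shared step was not tested. Fewer ciliated cells and lower transcription per ciliated cell also stay open, as effects of the genotype that were not tested, and either may hold.

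Interferon response genes were higher (median 0.99), and if more immune cells were the whole cause, genes common to immune cells would rise as far, yet the interferon genes rose beyond them by 1.12 (SE 0.27) over members above the median signal. Of 24 measured immune genes 2 rose, Lcp1 (0.53) and Lyz2 (0.97), and 0 fell; 18 of the 24 were above the median signal, and 5, 4 and 2 of the 24 also stand in the myeloid, antigen presentation and lymphocyte lists. The mean of those 18 differed by 0.075 (SE 0.19). Bright ones, chosen after their values were seen, went both ways without passing. Among them were Laptm5 (0.36), Fcer1g (0.71), Cd52 (0.44) and the class II genes Cd74 (-0.26), H2-Aa (-0.64), H2-Ab1 (-0.52) and H2-Eb1 (-0.66). The class II genes pull that mean down. Of the lists fixed beforehand, bright myeloid markers rose by 0.50 (SE 0.23) and 4 bright lymphocyte genes by 0.43 (SE 0.19). Bright interferon genes rose by 1.20 (SE 0.19), so more immune cells may account for part of the rise. A single mouse does not carry the pattern, since the lowest median without 1 mouse was 0.88. A response of the tubal cells to the transgene may underlie it, which these data did not test.

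Myeloid markers differed most between genotypes at 7 weeks, with medians of 0.89, 0.25 and 0.16 at 7, 8 and 9 weeks. Neutrophil and ovarian genes were high in repeat 2 of the 7-week transgenic mouse, and in its repeat 1 S100a8 (10.16), S100a9 (8.77) and Inha (8.06) also lay above the 7-week wildtype arrays (at most 6.53, 6.39 and 7.43). Not all values go that way: Gdf9 in that repeat 1 (8.39) lay below repeat 1 of the 7-week wildtype mouse (8.69), and repeat 2 of the 8-week wildtype mouse was higher for S100a8 (10.28) and S100a9 (8.86). Without repeat 2 the list mean differed by 0.80 more at 7 than at 9 weeks (SE 0.12 from repeat arrays). With all arrays this value was 0.98. The 0.80 lay above a bound of 0.4, set before this test but after the data had singled out repeat 2. That bound took the array kept to be free of other tissue, and the SE leaves out the spread between mice. Other tissue might therefore still be the source. A feature of that mouse, such as its cycle stage or a local infiltrate, and an effect of age on the genotype difference were not tested and stay open as well.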

How the results depend on the processing

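Removal of dim probes, normexp with quantile normalization and the array left out were chosen only after the data were seen; the other alternatives were planned. No called result reversed. Of 2883 values of 127 named genes under alternatives, 2552 kept direction and side of the threshold, 321 lost the call, 5 gained it and 5 changed sign uncalled; of 702 values of 27 lists these numbers were 635, 30, 18 and 19. Probe counts were 1091 higher and 1137 lower without the dimmest 50% of probes (fewer probes tested), 3241 and 3362 with array quality weights, 662 and 669 without both 8-week mice, 800 and 762 without both 9-week mice (fewer mice), 403 and 373 at 2-fold or more, and 792 and 760 at an adjusted p below 0.01 (stricter thresholds). Leaving out 1 mouse gave 873 to 1815 higher and 858 to 1857 lower probes. It gave 0 to 254 for the interaction, with 1 residual degree of freedom, and 0 for the age trend. Without the 8-week transgenic mouse 82 of 116 named calls remained. With the mouse as a random block, which counts repeat arrays partly as separate mice, 7 probes passed for the interaction and 15 for age. With the replicate block these were 4 and 20, genotype counts were 2185 and 2287, and the endothelium and oxidative phosphorylation lists lost their calls; Sprr2f, Uqcrb and Zeb2 lost theirs too, and it changed no other list call and moved no other count by over 1.5 times. Without the repeat 2 array of the 7-week transgenic mouse 1616 and 1721 probes passed. The median correlation of differences between ages was 0.786 without the dimmest 50% of probes and 0.651 on repeat 2 arrays. With an estimated correlation 0 lists passed, and mitosis (median 2.30), S phase (1.86), ciliated cell (-1.02) and interferon response (0.99) were among the 11 that lost the call. Apart from that setting, those 4 lists and DNA repair, smooth muscle and mesothelium passed in all 25 alternatives, antigen presentation in 22, myeloid in 23, endothelium in 20 and oxidative phosphorylation in 16. Normexp with median scaling lowered the share of higher among called probes from 49.0% to 41.3%, with a median of all probes of -0.04. Calls lost under another scaling were those of Cald1, Mrc1, Parp1, Cxcl9, Dnajb1, Meis1 and Cox8a. Except where given, the cause was not tested. No filter equals the setting used, since all probes with values were tested; the stricter detection filter and the BeadChip block were not run, for lack of columns matched to samples. Signal over background limits the dim genes: the 5th percentile of an array lay between 74.9 and 121.3.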

Other observations

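The groupings, tests and genes here were chosen only after the values were seen. Histone genes parted by family. Of 14 H2A genes 9 were higher and 1 lower, H2ac18 (-1.65), with a median log2 difference of 2.58, led by H2ac7 (3.73) and H2ac15 (3.69). Of 11 H2B genes 0 were higher by limma and 8 lower, with a median of -1.04, among them H2bc6 (-1.36) and H2bc4 (-1.32). H3 genes had 5 of 9 higher and 0 lower (median 0.47), H4 genes 1 of 10 higher and 1 lower (median 0.09), and linker histones 1 of 3 higher and 1 lower (median 0.04). Each family's median kept its sign under the other scalings, with H2A from 2.54 to 2.68 and H2B from -1.15 to -1.02. H2A and H2B are made in equal amounts as a dimer in S phase. Most replication-dependent histone transcripts end in a stem-loop without a poly(A) tail, and the labelling here was primed from poly(A) tails, so these values count the tailed transcripts. The copies within a family are near-identical, and their probes can share transcripts.

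Antigen presentation split by class. Of 14 class I genes, including their peptide loaders and proteasome subunits, 12 were higher and 0 lower, with a median of 1.02. Of 9 class II genes 0 were higher and 2 lower, H2-Ob (-0.97) and Ciita (-0.42), with a median of -0.46. The class I activator Nlrc5 rose by 1.17 (SE 0.16), and H2-Aa differed by -0.64 (adjusted p = 0.171). In the ciliated cell list Drc3 (-1.88), Pifo (-1.61) and Tppp3 (-1.52) fell; of the transcriptional regulators in it, Foxj1 (-0.49) and Rfx2 (-0.70) fell, and Mcidas (0.01), Rfx3 (-0.05) and Myb (0.09) did not pass. In smooth muscle Tagln (-1.52), Lmod1 (-1.45), Actg2 (-1.39) and Myh11 (-1.04) fell, while the bright Acta2 differed by -0.08 (adjusted p = 0.569). The complement genes C1qa (0.78), C1qb (0.75) and C1qc (0.83) rose while Cd163 (-0.97) and Mrc1 (-0.67) fell. In the secretory list the antioxidant Gpx3 fell by 1.16.

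The repeat arrays of a mouse differed in more than brightness. Besides Adipoq, the lipid enzyme Scd1 was lower in repeat 2 than in repeat 1 of the wildtype mice, by -2.35, -1.69 and -0.75 at 7, 8 and 9 weeks, and of the transgenic mice by less, -0.59, -0.27 and -0.091. The oocyte gene Gdf9 was higher in repeat 2 by 2.18 in the 7-week transgenic mouse and lower by -1.27 in the 7-week wildtype mouse. Of variation between mice of 1 genotype, the repeats of a mouse shared r of 0.591, 0.812 and 0.688 across probes above the median signal, which are not independent replicates, in the wildtype mice of 7, 8 and 9 weeks. In the transgenic mice r was 0.569, 0.168 and 0.348, and repeat 1 at 8 weeks correlated at 0.211 with repeat 2 at 9 weeks, above its own 0.168. The first principal component, which separated the genotypes, held 54.9% of the variance and the second 14.2%.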
